A study of Arabidopsis thaliana with 12 samples.

How the data were processed

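The leaf samples of Arabidopsis thaliana, 12 in all and each on 1 array labelled with a single dye, were analysed as 6 time points of 2 replicates each. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, 0.5 µg of RNA was used per sample. Per the file headers, the arrays were scanned and quantified by the authors with Agilent Feature Extraction 10.5.1.1, and the deposited files hold the intensity of each spot on a linear scale (raw, background and processed signal) with marks for spots that are well above background, saturated or outliers. The processed signal is background-corrected by that program, and no scaling between arrays is recorded in the headers. The deposited series table holds log2 values of the same 15013 probes, and how they were made is not given in the sources used here. Set against the scanner values of probes well above background, its columns had r of at least 0.995 and a slope between 0.956 and 1.02, except for a slope of 1.28 for the second dark 16 h array. The medians of its columns all lie at 1.37, as after quantile normalization. Its scale is therefore log2 and its centring common to all arrays, and the exact method stays unknown.

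The log2 of the processed signal minus each array's 75th percentile was used as the level. On 11 of the 12 arrays under 50% of probes were well above background (26.5 to 41.2%, and 52.2% on the second dark 16 h array), so the percentile was taken over the 2876 probes well above background on all 12 arrays. Control spots (536, with 77 negative controls among them) were left out, as were spots marked as outliers (0 to 9 per array); no probe was saturated. The 15013 probes carry 5154 transcript names, 4785 of them with 3 probes. A transcript's value is that of its probe with the highest mean signal. A transcript was tested if that probe was well above background on both arrays of at least 1 time point, which left 3302. Where a probe was not well above background on any array of a group, the text gives the brighter over the dimmer group as "at least N-fold". This bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The depth of an array cannot be counted as reads can, and the precision is limited by the number of arrays and, for dim transcripts, by signal over background.

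Of the transcript names, 479 are locus codes of 405 loci, of which 400 were found in the gene table used here (assembly TAIR10.1). Of the 173 microRNA precursor names, 164 matched a symbol there. The 4499 names with a TU code have no gene name in any table used here, and at most a few are printed. The array headers name an older build than the table, so no coordinates are given.

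Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were an F test over the 6 time points, a cosine and sine of 24 h period, the mean of the 3 dark minus the mean of the 3 light time points, and the 5 steps between consecutive time points. The cosine was fitted without time point means, so its residual spread also holds departures from a smooth course. The other comparisons used 1 mean per time point. Errors are standard errors of the fitted difference. Residual degrees of freedom were 6 in the fit with 1 mean per time point. Gene lists were tested with camera at a preset correlation of 0.01 and with fry, for lists with at least 5 members. Classes were compared with Fisher's exact test, two-sided, over the transcripts tested. On simulated data for 3288 transcripts, with 100 changed 2-fold and 100 changed 4-fold, the F test recovered 1% of 2-fold and 11% of 4-fold changes at a single time point. The step to 16 h recovered 4% and 48%, the cosine 4% and 75% of 2-fold and 4-fold peak-to-trough courses, and dark minus light 50% and 96%. False calls made up 0%, 1.89%, 4.82% and 6.41% of the calls in these 4 settings. Among recovered cosine courses the median error of the peak time was 0.47 h. The simulated noise was normal, with 1 SD per transcript on all 12 arrays, unrelated to signal and without a slide difference. In the data the replicate SD (log2) ran from 0.382 at 4 h to 0.799 at 16 h. The simulated shares may therefore not carry over to the data, least of all for the step to 16 h.

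Named transcripts followed a rule fixed before the data were examined. For the cosine these were the 4 largest peak-to-trough courses for each of the 6 peak times. For dark minus light they were the 10 largest rises and 10 largest falls with all 6 dark arrays on one side of the 6 light arrays, and for each step the 3 largest rises and 3 largest falls. The rule adds 2 to 4 members of each gene list, each known non-coding RNA detected, and a fixed set of clock genes with FLORE. Symbols came from the fixed lists or the gene table, in which CHE is listed as TCP11, and PIF1 and PIF5 also go by PIL5 and PIL6.

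Alternatives fixed before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, the authors' series table, no filter on dim probes, a filter on all 12 arrays, the mean of a transcript's probes, the replicate number as a block, slide as a block, at least a 2-fold change, and leaving out each array. That plan also held a fit of 2 groups of 6 arrays for dark minus light, a mean-variance trend for the F test, and an estimated correlation for camera. Normexp used the median raw signal of each spot, because the mean raw signal was not analysed here. Scaling on all probes, array weights, leaving out both dark 16 h arrays, fits within a single slide, slide as a block for the gene lists and a model of classes with signal were chosen after seeing the data. Slide and scan day coincide in the headers and count as 1 batch.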

Results

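Leaf RNA of Arabidopsis thaliana Col-0, the reference accession, was measured on 12 one-colour Agilent arrays whose probes target long non-coding RNAs, microRNA precursors and a small set of protein-coding genes. Plants were 30 days old and grown at 22 °C and 65% humidity with 145 µmol per m2 per s of light, in days of 8 h light and 16 h dark. The titles name 6 time points with 2 replicates each: light at 0, 4 and 8 h, and dark at 12, 16 and 20 h. The series title speaks of continuous light, while the sample titles and the growth protocol speak of light and dark. Light and dark are therefore used here only as names taken from the titles, and it stays open whether the lamps were off at 12, 16 and 20 h. The labels do not say whether replicates came from separate plants, so p-values measure the spread between replicate arrays, which may be technical. Those of the cosine also take in departures of time points from the fitted course.

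Between 3983 and 7832 of the 15013 probes were well above background per array, and 2876 probes were so on all 12. The second dark 16 h array held the 7832, and the next highest array held 6186. Replicates correlated with r from 0.909 (dark 16 h) to 0.98 (light 4 h) across the 3302 transcripts tested, transcripts not being independent replicates. The arrays lay on 2 slides: the 4 arrays of 0 h and 4 h on slide 1, and the 8 arrays of 8, 12, 16 and 20 h on slide 2. The change from 4 h to 8 h therefore cannot be told apart from a difference between slides. Every other range or contrast below that sets 0 h or 4 h against a later time point also holds any such difference. Having 2 replicates per time point limits the precision of every value below.

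**Figure D1:**
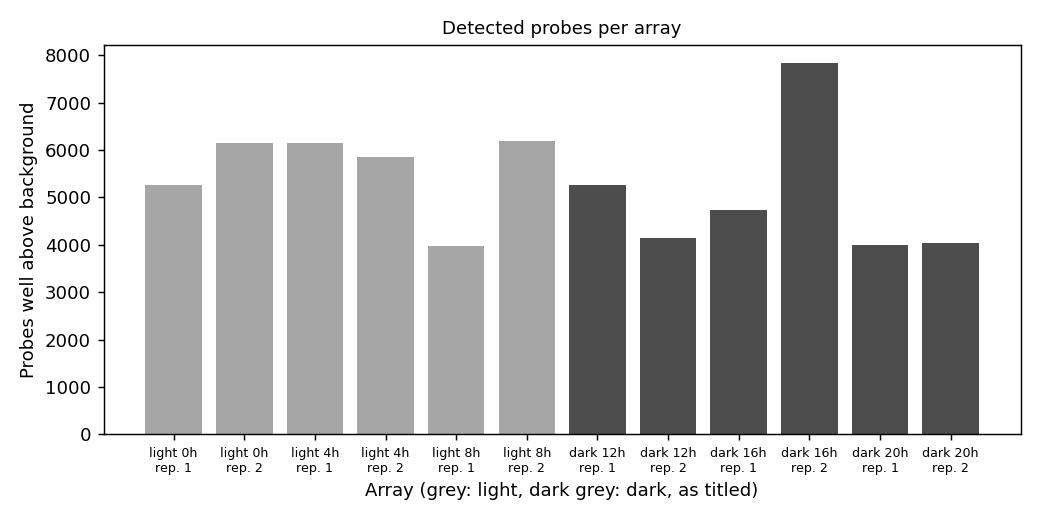
Bars give the number of probes well above background on each of the 12 arrays, out of 15013. The second dark 16 h array stands at 7832 and the other 11 arrays between 3983 and 6186.

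The first comparison asked which transcripts varied over the 6 time points at all. Clock and cold-regulated genes were among those with wide ranges. LHY, a MYB transcription factor of the morning part of the clock, differed by 8.10 ± 0.19 (SE) on the log2 scale between its highest time point (8 h) and its lowest (20 h). Its range was 274-fold, with adjusted p = 1.4e-06 in the F test over the 6 time points. Its partner CCA1 ranged over 7.27 ± 0.21, or 155-fold, between the same time points. COR15B, a cold-induced chloroplast protein gene, ranged over 7.68 ± 0.18 between 8 h and 16 h, or 205-fold. AT5TU002520 ranged over at least 124-fold by its brightest probe, being not well above background at its lowest time point. Across its 3 probes the difference between 16 h and 4 h ran from 0.80 to 8.91. The clock gene CHE ranged over 0.95 ± 0.20. PRR9 and PRR7, pseudo-response regulators that repress CCA1 and LHY, ranged over 6.90 ± 0.18 and 6.76 ± 0.28, both lowest at 0 h and highest at 12 h. These time points lie on different slides. Within slide 2 the means ran from -2.24 (20 h) to 4.05 (12 h) for PRR9 and from 1.95 to 6.19 for PRR7. Among annotated non-coding RNAs, FLORE ranged over 4.81 ± 0.17 (28-fold) between 20 h and 8 h. In limma's moderated F test with Benjamini-Hochberg adjustment, 485 of the 3302 transcripts (14.7%) passed an adjusted p of 0.05. Of these, 127 were highest at 16 h and 108 at 12 h, against 67 at 0 h, 71 at 4 h, 48 at 8 h and 64 at 20 h. Under the 5 other scalings the same 485 were most often highest at 12 h (122 to 170), with 42 to 101 highest at 16 h. Within slide 2 alone, 138 transcripts varied among the 4 time points. With single arrays left out the count lay between 257 (without the first 4 h array) and 1274 (without the first dark 16 h array), and without both dark 16 h arrays it was 536.

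The second comparison asked which transcripts followed a smooth course with 1 peak in 24 h. The succession of the clock genes is one of fitted peaks, read between samples 4 h apart. Their highest means fell at 8 h for LHY and CCA1, 12 h for PRR9 and PRR7, and 16 h for PRR5, PRR3 and TOC1. The fitted peaks fell at 6.3 h for LHY, 7.4 h for CCA1, 10.8 h for PRR9, 13.1 h for PRR7, 17.7 h for PRR3 and 20.1 h for TOC1, the evening gene that opposes CCA1 and LHY. PRR5 was highest at 16 h, with a fitted peak at 16.5 h, but did not pass the cosine test (adjusted p = 0.17) while it passed the F test. The fitted peak-to-trough distance was 8.93 on the log2 scale for LHY, 8.30 for CCA1, 6.75 for PRR9, 6.65 for PRR7 and 4.29 for PRR3. PIF4, a bHLH factor of light and growth control, peaked at 13.9 h with a peak-to-trough distance of 4.65. FLORE, the non-coding RNA that overlaps CDF5 in the gene table, peaked at 20.7 h with 4.59. The cold-regulated genes COR15A and COR15B peaked at 18.4 h and 18.5 h with 5.36 and 5.61. The non-coding RNA AT2G35637 had the opposite course to PRR9 and PRR7 at its extremes: its peak lay at 1.1 h and its lowest mean at 12 h, 3.61 ± 0.18 below 0 h.

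**Figure D2:**
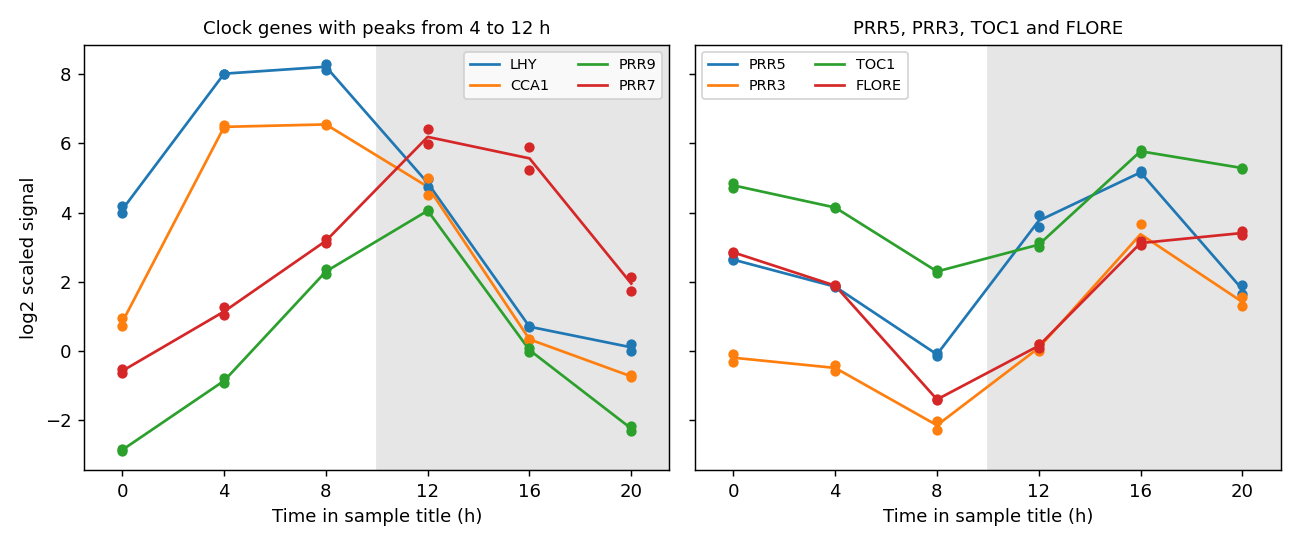
Points are the 2 arrays of each time point and lines join their means; the x axis is the time in the sample title in h, the y axis is log2 signal scaled to each array's 75th percentile, and grey marks time points titled dark. LHY and CCA1 are highest at 4 and 8 h, PRR9 and PRR7 at 12 h, and PRR5, PRR3 and TOC1 at 16 h, while FLORE is lowest at 8 h.

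In all, 151 of 3302 transcripts followed the cosine at an adjusted p of 0.05 in limma's moderated F test, and 138 of them also passed the F test over time points. Their peaks were spread over the sampled times, with 16 nearest 0 h, 26 nearest 4 h, 23 nearest 8 h, 33 nearest 12 h, 17 nearest 16 h and 23 nearest 20 h. Of the 24 transcripts named by the rule for this comparison, 14 carried only a TU code, which the files do not pair with a gene name. Among those, AT1TU001270 was highest at 0 h and lowest at 12 h, 4.84 ± 0.43 apart, and AT4TU026290 was highest at 8 h and lowest at 20 h, 5.07 ± 0.34 apart. AT1TU001270 has 2 probes, and the dimmer one differed by 0.75. The 3 probes of AT4TU026290 differed by 5.04 to 6.45. Leaving out single arrays moved the count of 151 to between 59 (without the first 4 h array) and 166 (without the second dark 16 h array); it was 72 without the first dark 16 h array. With a term for slide the cosine called 220 transcripts, 94 of them shared with the fit without it, and 14 of the 24 named transcripts passed, AT1TU001270 not among them. One cycle was sampled, so recurrence was not tested.

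Dark minus light compared the mean of the 3 time points titled dark with the mean of the 3 titled light. Its errors and p-values carry replicate spread only, and treated as 2 groups of 6 arrays 1 transcript passed. Higher and lower refer to these means, and single time points can go the other way. CCA1 stood at 0.84 at 0 h and 4.74 at 12 h, and PRR9 at 2.30 at 8 h and 0.03 at 16 h. The clock list moved both ways, by when each gene peaked. LHY had a lower dark than light mean by 29.5-fold (log2 -4.88 ± 0.11, adjusted p = 3.4e-07) and CCA1 by 9-fold (-3.17 ± 0.12). PRR7 was higher by 3.31 ± 0.16, PRR3 by 2.57 ± 0.14, PRR5 by 4.29-fold, PRR9 by 1.08 ± 0.10, TOC1 by 0.97 ± 0.10 and CHE, a TCP factor that binds the CCA1 promoter, by 0.66 ± 0.12. Scaling on all probes ended the calls for PRR9, TOC1 and CHE, and leaving out the first 4 h array that for CHE (adjusted p = 0.053). All 8 clock genes on the array thus passed the test, 6 higher and 2 lower, and all 8 passed the F test, both over all transcripts and adjusted over the list alone, though in the F test CHE failed on leaving out 8 of the 12 arrays and under 2 of 5 other scalings. For the clock list, camera gave a shift towards dark (adjusted p = 0.00053 with a preset correlation, adjusted p = 0.018 with an estimated correlation). Its members' median was 1.03 and their mean 0.33. With limma's fry the adjusted p was 0.0015 for a shift on balance and 6.4e-11 for changes in either direction. The list's adjusted p in camera was 0.22 with slide as a block and 0.45 within slide 2, where only 8 h stands for light.

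Of the 10 light-signalling genes on the array, 8 passed the F test over all transcripts and 10 did so adjusted over the list alone; PHYA and PIF1 each lost that call on leaving out 9 of the 12 arrays and under 4 and 2 of 5 other scalings, HY5 on leaving out 2 arrays and under 1 scaling, and PHYB under 1 scaling. Between dark and light, PIF4 was higher by 2.72 ± 0.12 (6.6-fold) and FHY1, which carries phytochrome A into the nucleus, by 0.50 ± 0.12. HY5, a bZIP factor that promotes light responses, was lower by 1.64-fold (-0.71 ± 0.10), HFR1 by 1.6-fold (-0.68 ± 0.12) and the photoreceptor gene PHYB by 1.37-fold (-0.45 ± 0.12). The calls for PHYB and FHY1 stood at the threshold (limma adjusted p = 0.05 and 0.044): leaving out any of 10 and 11 single arrays ended them (adjusted p up to 0.14), and so did 4 of 5 other scalings. For HY5 and HFR1 scaling on all probes ended the call, and for HY5 so did the mean of its probes. PIF5 varied by 2.43 ± 0.21 over the day, highest at 12 h and lowest at 0 h, but its dark and light means differed by -0.07 ± 0.12. COP1, PHYA, PIF1 and PIF3 had differences between -0.06 and 0.10 that did not pass. As a list the genes did not shift against the other transcripts (camera, adjusted p = 0.91, and 0.92 with an estimated correlation). With limma's fry the adjusted p was 0.0076 for a shift on balance and 6.5e-09 for changes in either direction, while the median was -0.03 and the mean 0.14.

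Both cold-list genes on the array had a higher dark than light mean. Not every dark time point was higher: COR47 stood at 7.69 at 0 h, above its 12 h (7.01) and 20 h (7.51) means. COR15A rose by 3.35 ± 0.15 (10.2-fold, adjusted p = 3.3e-05) and COR47, a dehydrin, by 0.85 ± 0.14 (1.81-fold). Both were highest at 16 h and lowest at 8 h, with ranges of 7.47 for COR15A and 2.02 ± 0.25 for COR47. The spot of COR15A on the second dark 16 h array was marked as an outlier and left out, so its 16 h value rests on 1 array and no error is given for its range. Of the 4 known non-coding RNAs on the array, FLORE had a higher dark than light mean by 1.11 ± 0.10 (2.16-fold). Its 12 h mean (0.15) nevertheless lay below those of 0 h (2.85) and 4 h (1.89). ASCO, which binds splicing regulators, was lower by 1.43-fold (-0.51 ± 0.10) and ranged over 1.65 ± 0.17 between 4 h and 16 h. TAS4 and ELENA1 had dark minus light differences of -0.11 ± 0.12 and -0.23 ± 0.24, and passed neither this test nor the F test. Scaling on all probes ended the dark minus light calls for COR47 and FLORE, and the F test call for COR47. The call for ASCO was ended by 3 of 5 other scalings, by the mean of its probes, and by leaving out either 4 h array (adjusted p up to 0.064).

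**Figure D3:**
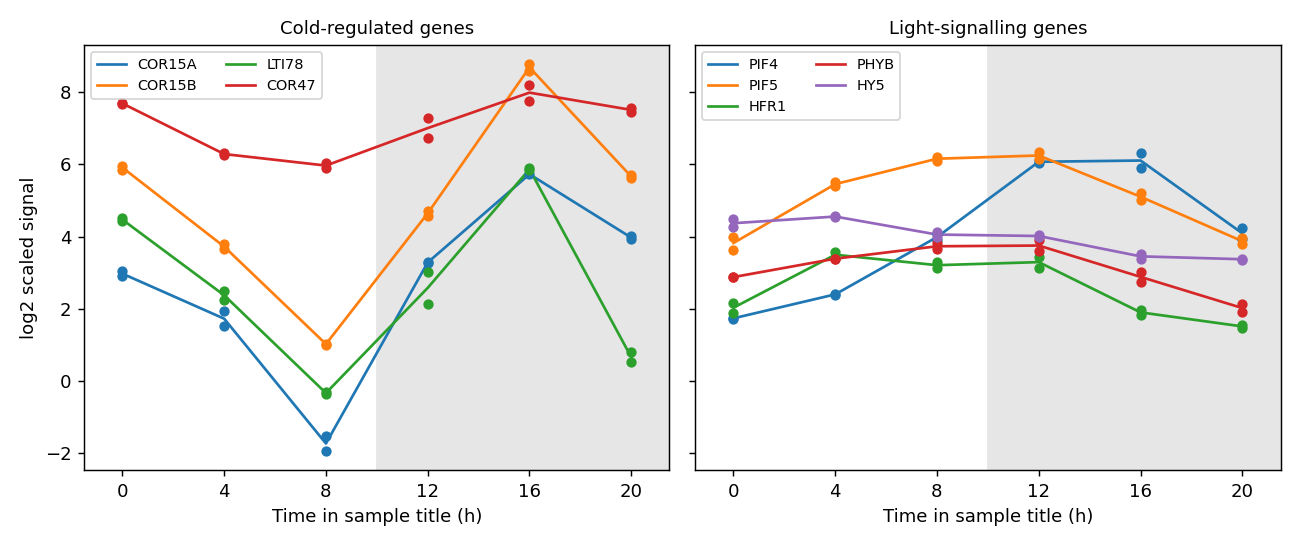
Points are the 2 arrays of each time point (1 for COR15A at 16 h) and lines join their means; the x axis is the time in the sample title in h, the y axis is log2 signal scaled to each array's 75th percentile, and grey marks time points titled dark. COR15A, COR15B, LTI78 and COR47 are lowest at 8 h and highest at 16 h, and PIF4 is 4.38 on the log2 scale higher at 16 h than at 0 h. Those 2 time points of PIF4 lie on different slides, and within slide 2 its means run from 3.98 at 8 h to 6.11 at 16 h.

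Across all transcripts, 336 of 3302 differed between dark and light in limma's moderated test, 154 higher and 182 lower. For 29 of the higher ones all 6 dark arrays lay above all 6 light arrays, and for 30 of the lower ones all lay below, 59 in all. Other splits of the whole time points into 3 and 3 gave between 5 and 79 such transcripts, and 3 of the 10 splits, the real one included, gave at least 59. The 20 largest changes of that kind, 10 each way, included PRR3 and NRPD1B, the largest subunit of RNA polymerase V, higher by 1.55 ± 0.19, though 1 of its 3 probes went the other way. The precursor of MIR852 was higher by 0.82 ± 0.17, a call that 7 of the 12 single arrays left out and 4 of 5 other scalings ended. The non-coding RNA AT4G17098 was lower by 3.49-fold (-1.80 ± 0.11) and the precursor of MIR171b by 2.34-fold (-1.23 ± 0.11). The other 15 had TU codes only, 7 higher and 8 lower, such as AT3TU007380 (4.58-fold) and AT1TU040590 (-2.36 ± 0.19, with 2 of its 3 probes going the other way). Among the dark arrays the probe used for AT1TU040590 was well above background on the first 12 h array alone, so the size of its fall is uncertain. Of the 20, 8 had a probe of opposite sign. Within slide 2, where 8 h alone stands for light, 28 transcripts passed. Of the 20 named changes 7 passed there. The contrast carries replicate spread only: treated as 2 groups of 6 arrays, 1 transcript passed, and 5 with slide as a block. With single arrays left out, between 144 (without the first 4 h array) and 704 (without the first dark 16 h array) passed, and of the 704 66.6% were higher, against 45.8% of the 336; without both dark 16 h arrays 257 passed, 35% of them higher. Scaling on all probes gave 43 higher and 90 lower, and moved the median of all transcripts from -0.09 to -0.20.

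From 0 h to 4 h, CCA1 rose by 5.63 ± 0.21 (49.6-fold, adjusted p = 1.7e-05) and LHY by 3.92 ± 0.19 (15.1-fold). AT5TU006260 rose by 2.52 ± 0.36. The non-coding RNA AT5G53048 fell by 2.45 ± 0.19, the precursor of MIR399d, a microRNA of phosphate starvation, fell by 2.33 ± 0.31, and COR15B fell 4.59-fold. In total 13 transcripts rose and 15 fell in limma's moderated test at an adjusted p of 0.05. The calls for MIR399d and AT5TU006260 were lost on leaving out 6 of the 12 arrays (adjusted p up to 0.15 and 0.22) and under 2 and 1 of 5 other scalings, and those for AT5G53048 and COR15B were lost with scaling on all probes. The count of 28 became 2 within slide 1 alone, 5 without either 0 h array and 52 without either dark 16 h array, and scaling on all probes left 2 higher and 1 lower.

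From 4 h to 8 h, FLORE fell by 3.29 ± 0.17 (9.75-fold, adjusted p = 0.00018) and COR15A by 3.47 ± 0.24. AT2TU063000 fell by 2.90 ± 0.17. By its brightest probe, AT5TU002520 was not well above background on any array of 0 h or 4 h and was so on all 8 later arrays. It was at least 95.2-fold brighter at 8 h than at 4 h, but its 3 probes differed in size, by 0.80 to 8.91 between 4 h and 16 h. AT3TU037980 rose by 3.77 ± 0.56, a call lost on leaving out 8 of the 12 arrays (adjusted p up to 0.18). In all, 25 transcripts rose and 17 fell in limma's moderated test. The balance was not stable: without the first or second 8 h array 22 and 38 passed, 27.3% and 23.7% of them higher against 59.5%, array weights gave 214 with 36% higher, and without either 4 h array 14 passed. This step runs between the slides, and no value within a slide can be had for it.

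From 8 h to 12 h, over which the titles pass from light to dark, COR15A rose by 5.03 ± 0.24 (32.6-fold, adjusted p = 0.00014), PRR5 by 3.86 ± 0.20 (14.5-fold) and COR15B by 3.63 ± 0.18 (12.4-fold). LHY fell by 3.36 ± 0.19, AT3TU037980 fell by 2.97 ± 0.56 (a call lost on leaving out 10 of the 12 arrays), and AT5TU048970 was at least 2.93-fold dimmer, being not well above background at 12 h (a call lost under normexp with quantile normalization). In limma's moderated test 69 transcripts rose and 46 fell. Within slide 2 alone 11 passed, and without the first 8 h array 27 did. Scaling on all probes left 10 higher and 4 lower, where quantile normalization left 21 and 21.

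From 12 h to 16 h, CCA1 fell by 4.40 ± 0.21 (21.2-fold, adjusted p = 3e-05), LHY fell by 4.15 ± 0.19 (17.7-fold) and PRR9 fell by 4.02 ± 0.18 (16.3-fold). The largest rises were in TU-named transcripts not well above background at 12 h. AT3TU043230 was at least 9.18-fold brighter at 16 h, with scaled log2 values of -5.25 and -0.97 on the 2 arrays, and lost its call on leaving out 11 of the 12 arrays (adjusted p up to 0.12; without the second 16 h array 0.056). AT1TU044590 was at least 7.56-fold brighter, with -4.66 and -2.12, and lost its call without the first 12 h array (adjusted p = 0.082). Both calls were lost under normexp with quantile normalization. In limma's moderated test 203 transcripts rose and 110 fell, while the median of all transcripts moved by 0.36 (by -0.28 under quantile normalization and -0.71 with scaling on all probes). Without the second dark 16 h array 148 passed (43.2% higher, against 64.9%), without the first 1078 (85.8% higher), and within slide 2 alone 58. Leaving out 1 array of another time point gave 159 to 219. The balance of the calls turned with the scaling: quantile normalization gave 92 higher and 179 lower, normexp with quantile normalization 130 and 221, the authors' series values 98 and 185, median scaling 179 and 148, and scaling on all probes 109 and 325.

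From 16 h to 20 h, LTI78, a gene induced by cold, drought and abscisic acid, fell by 5.22 ± 0.29 (37.2-fold, adjusted p = 0.00011). The non-coding RNA AT3G61198 rose by 2.86 ± 0.22 (7.25-fold, adjusted p = 4e-04), and the precursor of MIR838 was at least 3.81-fold brighter at 20 h, a call lost on leaving out 9 of the 12 arrays (adjusted p up to 0.12). AT3TU021550 was at least 5.22-fold dimmer at 20 h, a call lost on leaving out 5 of the 12 arrays. Its scaled log2 values on the 2 arrays of 16 h were -4.94 and -2.11, and without the second its step was -3.06 rather than -4.47. In limma's moderated test 91 transcripts rose and 189 fell, and the median of all transcripts moved by -0.39 (by 0.31 under quantile normalization and 0.58 with scaling on all probes). Without the second dark 16 h array 135 passed, without the first 1084, and within slide 2 alone 55. Leaving out 1 array of another time point gave 101 to 249. Here too the balance turned: quantile normalization gave 149 higher and 111 lower, normexp with quantile normalization 310 and 169, the authors' series values 131 higher of 236, median scaling 163 and 159, and scaling on all probes 171 and 91. Changes of named genes at these 2 steps are to be read against those shifts of the median.

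The kinds of transcript differed in how often they varied over time. Of the protein-coding genes on the array, 49 of 91 tested (53.8%) passed the F test, against 118 of 358 annotated non-coding RNAs (33%), 38 of 125 microRNA precursors (30.4%) and 278 of 2719 TU-named transcripts (10.2%). Annotated non-coding RNAs passed more often than TU-named transcripts (odds ratio 4.31, adjusted p = 3.3e-26), as did microRNA precursors (3.83, adjusted p = 2.4e-09), and protein-coding genes passed more often than annotated non-coding RNAs (2.37, adjusted p = 0.00039; Fisher's exact test, two-sided, 3 tests). The protein-coding set was chosen by the array's makers and includes many clock and light genes. TU-named transcripts were also dimmer, with a median scaled log2 signal of -5.17 against 0.02 for annotated non-coding RNAs, and with signal in the model the odds ratio between those was 1.99. With scaling on all probes the differences from TU-named transcripts no longer passed (odds ratios 1.01 and 1.43), and without the first dark 16 h array the odds ratios were 1.46 and 1.66. They were higher, 7.77 and 5.97, with the mean of each transcript's probes, and 11.3 and 4.03 under normexp with quantile normalization. Under the authors' series values they were 2.69 and 1.91, and under quantile normalization 2.93 and 1.98. Among transcripts well above background on all 12 arrays, protein-coding genes no longer differed past the threshold from annotated non-coding RNAs (odds ratio 1.66, Fisher's exact test, p = 0.07). Transcripts are not independent replicates, so these tests describe these arrays.

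Of the 15 gene lists fixed before the data were examined, 4 had members on the array, described above. No member of the other 11 was on it: photoperiodic flowering, photosynthesis, dark and sugar starvation, starch metabolism, flavonoid synthesis, growth and auxin, reference genes, and markers of guard cells, epidermis and trichomes, vascular tissue, and meristem and dividing cells. GI and CDF5, which the rule for named genes lists, are not on the array. Sense and antisense pairs were not tested, because the gene table used here gives no strand and only 3 pairs of loci on the array overlap in it.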

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

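The tests of negative controls, of promoter probes and of the general shift of dim spots below were chosen after the result they measure was seen; the test of shared probes and the test of their level were written before.

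The array holds 9 probes for promoter regions of TMM and SDC, which target no transcript and enter no comparison. Of these, 3 were well above background and brighter than all 77 negative control spots on 1 array each, the second dark 16 h array: 1 for the plus strand of the TMM promoter, 1 for its minus strand and 1 for the SDC promoter. They drew attention as signal in data that the report does not use. The highest negative control there had a processed signal of 8.57, against 1.52 to 3.27 on the other arrays.

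The same array had 7832 probes well above background, more than any other. A raised scanner background is argued against by its negative controls, whose mean raw signal of 22.3 lies within the 18 to 23.3 of the other arrays. Template other than mature transcripts, such as genomic DNA, cannot be told from a general shift of dim spots: 8 of the 9 promoter probes lay above their value on every other array, 5 of them not well above background, but so did 69 of the 77 negative controls and 62.7% of 6630 other dim probes in the processed signal. Transcripts that rose at 16 h cannot be told apart from this either. Of its 1873 probes seen at no other time point, 4.43% were also well above background on the first 16 h array. For the other arrays this share was 0 to 77.6% (median 16.7%). The 0% came from the 20 h arrays, with only 4 and 7 such probes, and the second 8 h array had 1.27% of 158. The median rise of the 1873 probes was 0.42 on the log2 scale on the first 16 h array against 3.30 on the second. Without this array 148 transcripts changed between 12 h and 16 h, against 313 with it. Leaving out 1 array of another time point gave 159 to 219, so the fall in this count does not single out the second 16 h array.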

How the results depend on the processing

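Array weights, scaling on all probes, leaving out both dark 16 h arrays, fits within a single slide and slide as a block for the gene lists were chosen after seeing the data. Of 1233 values of named transcripts under other settings, 1079 kept their side of the threshold, 147 lost their call and 7 gained one; with 1 array left out, 1165 of 1354 kept it, 186 lost the call and 3 gained one. The sign turned for 0 values with a call, and for 13 and 2 values with none, of PIF1, PIF3, PIF5, PHYA and TAS4. Counts below are transcripts past the threshold, and except where a construction is named the cause was not tested. With normexp and quantile normalization the cosine gave 254, 4 h minus 0 h 91, 8 h minus 4 h 146, 12 h minus 8 h 242 and 20 h minus 16 h 479. Quantile normalization alone gave 18 for 4 h minus 0 h and 42 for 12 h minus 8 h, median scaling 18 for 4 h minus 0 h, and the authors' series values 26 for 8 h minus 4 h and 39 for 12 h minus 8 h. Scaling on all probes gave 92 for the cosine, 133 for dark minus light, 3, 25 and 14 for the first 3 steps, odds ratios of 1.01 (annotated non-coding against TU-named) and 1.43 (microRNA precursors against TU-named), and 4 light-signalling and 1 cold gene in the F test. With no filter on dim probes, which tests more transcripts, the F test gave 211, the cosine 59, dark minus light 158, the steps 6, 19, 25, 146 and 99, and the light-signalling list 5. Filtering on all 12 arrays, which tests 1520, gave 307 for the cosine, 79, 137 and 291 for the first 3 steps and an odds ratio of 1.66 for protein-coding against annotated non-coding, no longer past the threshold. Array weights gave 109, 214, 45 and 56 for 4 h minus 0 h, 8 h minus 4 h, 16 h minus 12 h and 20 h minus 16 h. Both arrays of a time point received the same weight (0.315 at 16 h, 2.24 at 4 h). This setting therefore weights time points and cannot single out the second dark 16 h array. A 2-fold minimum left 125 for dark minus light.

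As 2 groups of 6 arrays dark minus light gave 1, and 5 with slide as a block. Within slide 2 the F test gave 138 and dark minus light 28, and within their own slide the steps gave 2 (4 h minus 0 h), 11 (12 h minus 8 h), 58 (16 h minus 12 h) and 55 (20 h minus 16 h), with fewer arrays. The camera adjusted p of the clock list was 0.22 with slide as a block and 0.45 within slide 2. Slide as a term could not be fitted for the F test and steps, because whole time points lie on 1 slide. Without both dark 16 h arrays 4 h minus 0 h gave 52, while the F test gave 536, the cosine 147, dark minus light 257, 8 h minus 4 h 60 and 12 h minus 8 h 168.

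Replicate numbers showed no clear pairing of the arrays: the correlation of same-numbered deviations was -0.1 to 0.19 (median 0.072), over 0.1 in 5 of 15 pairs. A weak pairing is not excluded. With the replicate number as a block the cosine gave 95, the F test 471, dark minus light 293 and the steps 19, 31, 101, 323 and 280.

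With 1 array left out, the other array of its time point being assumed to vary like the other groups, the F test ranged from 257 (without the first 4 h array) to 1274 (without the first dark 16 h array), the cosine from 59 (without the first 4 h array) to 166, dark minus light from 144 to 704, and the steps from 5 to 52, 14 to 60, 27 to 168, 148 to 1078 and 101 to 1084. The light-signalling list had 5 to 9 members past the F test, the clock list 7 to 8 and the cold list 1 to 2, since without the first dark 16 h array COR15A has no value there. The odds ratios ranged from 1.46 to 4.32, 1.66 to 3.56 and 2.06 to 2.95, and the camera adjusted p from 7.7e-05 to 0.022 (clock) and 0.48 to 0.99 (light signalling). Sense and antisense pairs and their alternatives were not run. Signal over background limits dim transcripts: 1520 of the 3302 tested were well above background on all 12 arrays.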

Other observations

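Beside the cold list, other genes of cold and abscisic acid responses were on the array; they and the transcripts of the next paragraph were chosen after their values were seen. LTI78 was highest at 16 h and lowest at 8 h, 6.21 ± 0.29 apart on the log2 scale (74.2-fold). In limma's F test over the 6 time points its adjusted p was 5.8e-05. KIN1, a cold-induced gene, was highest at 16 h and lowest at 20 h (7.47-fold), and ABI5, a bZIP factor of abscisic acid signalling, was highest at 16 h and lowest at 8 h (5.87-fold). LTI65 was highest at 0 h (4.01-fold range). ABI1 and ABI2, phosphatases that restrain abscisic acid signalling, ranged over 2.99-fold and 2.43-fold, highest at 12 h and 16 h.

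Of the 38 microRNA precursors that passed the F test, 26 (68.4%) were lowest at 20 h, against 19 of 118 annotated non-coding RNAs, 16 of 49 protein-coding genes and 69 of 278 TU-named transcripts. Under normexp with quantile normalization, quantile normalization alone and the authors' series values 22 of the 38 were lowest at 20 h, under median scaling 25 and under scaling on all probes 19. The precursor of MIR163 was 11.6-fold lower at 20 h than at 12 h, that of MIR850 6.82-fold, that of MIR863 4.93-fold and that of MIR157c 3.89-fold. Those of MIR399c and MIR399d were at least 2.92-fold and at least 9.7-fold dimmer at 20 h than at their highest time point. That of MIR404 went the other way, highest at 20 h and lowest at 8 h (40.5-fold, 5.34 ± 0.97, limma adjusted p = 0.048). MIR167d was measured as a precursor (8.8-fold range) and as AT1G31173.1 (9.43-fold), both highest at 12 h. The non-coding RNAs AT5G53048 (38-fold) and AT4G03038 (19.8-fold) were also lowest at 20 h.

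The tests of time point order, of CCA1 within slide 1, of the order of clock peaks, of AT5TU002520 and of pairs without the 16 h arrays were chosen after the result was seen, and the others below were written before.

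CCA1 was low at 0 h, LHY stood near the middle of its range there, and both peaked at 6.3 to 7.4 h. Of 60 circular orders of the time points 1, the labelled one, had the shortest path through their correlations (0.293, next 0.297), a narrow margin. The highest correlation was that of 0 h and 4 h (0.974), which share slide 1 and are neighbours in the labelled order. The path therefore cannot decide whether labels are out of order. A difference between slides is argued against by the rise of CCA1 by 5.63 ± 0.21 within slide 1. The fitted peaks of LHY and CCA1, PRR9, PRR7, PRR5 and TOC1 followed one another with 0 steps out of order, though PRR5 did not pass the cosine test. Both a time zero other than the start of light and a clock delayed in continuous light predict this order, so these cannot be told apart.

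The 0 h and 4 h arrays, alone on slide 1, set against the rest called 266 transcripts, while 12 h and 16 h against the rest called 410. The 2 pairs above 266 both hold the 16 h arrays; without these arrays 0 h and 4 h called 322, and 8 h and 12 h, on slide 2, called 381. This argues against the slide as the largest split and leaves a smaller effect of the slide open. AT5TU002520 changed by -0.66 within slide 1 and ranged over 1.3 within slide 2, against 7.96 between slides. The SE of a difference between 2 time points was 0.81, and AT5TU002520 was well above background on 0 of 4 and 8 of 8 arrays. A transcript present only in the plants of one slide may account for it, as a hypothesis. These values are of its brightest probe, and its 3 probes were higher at 16 h than at 4 h by 0.80 to 8.91.

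For the cosine, 1 of the 60 orders, the labelled one, gave as many as 151 transcripts and the highest other gave 92. The labelled order keeps 0 h and 4 h, alone on slide 1, side by side, and many other orders part them. A slide difference could therefore favour the labelled order. The orders were not run with a term for slide, so chance is not excluded. For dark minus light as 2 groups of 6 arrays, 4 of 100 splits gave as many as the real one's 1 transcript, the highest other 3, a share under 0.05. Those splits part arrays of the same time point, which the real one keeps together, so on a count of 1 they do not exclude chance. With time points kept whole, 2 of 10 splits gave as many as the real 336; the highest other, 0, 4 and 20 h against the rest, gave 346, and 10 splits are too few for a share under 0.05.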
